A study of Mus musculus with 2 samples.

How the data were processed

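Messenger RNA was sequenced from mouse bone marrow-derived macrophages (BMDMs), which are macrophages grown in culture from bone marrow progenitors. The series holds 2 libraries. The DCA library came from cells given 100 µM deoxycholic acid, a secondary bile acid that gut bacteria make from cholic acid, for 24 h. The NC library came from cells collected without it. The vehicle of the NC cells is not given in the sources used here, and it is unclear from the labels whether collection followed directly on the 24 h of treatment or a day after it. Each library was placed in its group by its treatment label, and the columns of the table were matched to the libraries by name.

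The authors deposited FPKM (reads per kilobase of gene and 1e6 reads) for 15576 genes in both libraries, with Ensembl identifiers and symbols. Per the submitters' processing notes, STAR 2.5.0c, Picard 1.126, bedtools 2.17.0, HTSeq 0.6.0 and DESeq2 3.0 were among the tools and GRCm38 was the genome build. The notes used here give no role or order for them. The gene length used for the FPKM, the strand setting of the counting and any filter on the genes are not given in the sources used here. Of the identifiers, 15548 were found in the GENCODE vM21 annotation of GRCm38, which supplied coordinates, gene types, exon lengths and exon overlaps. Exons were taken to overlap by position alone, whatever their strand. For 240 genes without a symbol in the table the annotation name was used. Coordinates are 1-based.

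The deposited FPKM values keep the trace of whole reads. Ratios of low values between the libraries fell on fractions of whole numbers times a single constant, which gave a read total 4.66% larger in NC than in DCA. With the summed length of all annotated transcripts of a gene as its length, the values of 11371 of 11794 genes with fewer than 5000 reads (96.4%) came out as whole reads in both libraries within 0.05 of a read, against 1% by chance. The read totals behind the FPKM were then 56.6 M for DCA and 59.2 M for NC, and the rebuilt reads of the table summed to 99.5% of each. Summing transcript lengths makes the length of a gene with many transcripts too large. Its FPKM is therefore too low, levels of different genes cannot be compared, and a fixed filter or pseudocount weighs more on such genes. The ratio between the libraries does not depend on the length.

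The main measure was the difference in log2(FPKM + 1), DCA minus NC, which understates the ratio of genes with low FPKM. A gene was tested against the size limits if the mean of its FPKM values was at least 1, which left 9656 genes. With 1 library per group there was no statistical test, and no p-value or standard error was computed. Genes at least 2-fold apart on this scale were counted in each direction. Beside it, the ratio of rebuilt reads scaled to the read totals is given with an exact Clopper-Pearson 95% interval. These intervals cover counting error only, and they compare 2 libraries, not 2 conditions. Reads from PCR copies are not independent molecules, so the true counting error is larger. The median half-width of the interval was 5.36% of the ratio.

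In all, 33 gene lists were fixed before the data were examined, covering pathways a bile acid might act on, macrophage states, other cell types of a marrow culture and technical classes. For a list with at least 5 tested members, the median difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart at a percentile of at most 2.5 or at least 97.5. This describes these libraries. Genes of a list vary together, so list medians spread more widely than those of random lists, and the limits are too easily passed. Members at least 1.5-fold apart were counted.

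Genes are named in the report by a rule fixed at the same time. It takes the 12 genes with the highest and the 12 with the lowest difference among those with a mean FPKM of at least 5, passing over symbols that are only predicted gene or clone numbers (2 among the highest and 1 among the lowest). It adds, for each list, up to 2 members in each direction that are at least 1.5-fold apart, and 20 genes fixed by name, of which 18 were found in the table and some are not reported here. Other genes named, including the examples given for lists without such members, were chosen after their values were seen.

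The recovery of the read totals, the size limits, the counting intervals and the placing of lists were tested on simulated data over 9649 genes. These data were made from the mean of the DCA and NC values with counting noise only. A few genes were given another length than the annotated one. The relative error of the recovered ratio of totals was 1.2e-09. Of the genes changed 4 times, 100% passed the 2-fold limit, of those changed 2.5 times 86%, of those changed 0.4 times 51.1%, and of those changed 1.5 times 0%. No unchanged gene was 1.5-fold apart, and the 95% intervals of 4.73% of unchanged genes excluded equality. A planted list raised by 15 percent was placed at percentile 100 and an unchanged list at 24.45.

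Alternatives covered the pseudocount (0.1 and 5), the filter (none, and a mean FPKM of at least 5), rescaling each library to 1e6, centring on the trimmed mean, upper quartile scaling, the size limit (1.5-fold and 3-fold), random lists without matching, and the mean in place of the median. After the data were seen, matching on exon length, leaving out genes with overlapping exons, and FPKM rebuilt with the merged exon length were added. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.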

Results

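The expression of 15576 genes was measured by RNA sequencing in mouse bone marrow-derived macrophages (BMDMs). There was 1 library from cells treated with 100 µM deoxycholic acid for 24 h (DCA) and 1 from cells without it (NC). The read totals behind the FPKM values were 56.6 M for DCA and 59.2 M for NC, with M for 1e6 reads. The comparison asks which transcripts differ in macrophages after exposure to this bile acid. Every difference below is between single libraries and has no replicate check, so none can be set against the spread between cultures. Ratios are DCA over NC, with 95% intervals that cover counting error only.

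The libraries were close. Of the 9656 tested genes, 97.2% differed by less than 1.2-fold in FPKM + 1, a scale that understates the ratios of genes with low FPKM. On that scale, 15 genes were at least 2-fold higher and 9 at least 2-fold lower in DCA. The differences with the widest reach were small and shared by many members of a gene group. Markers of neutrophils and lymphocytes were higher in DCA in 20 of 20 and 9 of 9 tested members, with median ratios of 1.17 and 1.23. Cytosolic ribosomal protein genes were higher in 39 of 40 members, with a median ratio of 1.075. Interferon-stimulated, MHC class II and ATF4 target genes were higher by similar amounts, while genes of macrophage identity, the lysosome, the unfolded protein response and the NRF2 antioxidant response were lower by a few percent.

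Across genes, log2(FPKM + 1) correlated with a Pearson r of 0.994 and a Spearman rho of 0.992, and the differences had an SD of 0.148. Genes are not independent replicates. The median difference was 0.0067, and 53.5% of the tested genes were higher in DCA. Counts of higher members of a list are to be read beside that share. The libraries nevertheless lay further apart than the counting of independent reads gives. The robust SD of the differences, in units of that counting error, was 2.65, where independent reads alone give 1. PCR copies also raise this value, and their share is not known here. The counting interval excluded equality for 2482 genes higher and 1927 genes lower in DCA, 45.7% of those with rebuilt reads. At a limit of 1.5-fold, 33 genes were higher and 15 lower. The count of genes beyond the 2-fold limit moved with the settings, from 2 to 82 higher and from 2 to 34 lower among the pseudocounts, filters and scalings tried.

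**Figure D1:**
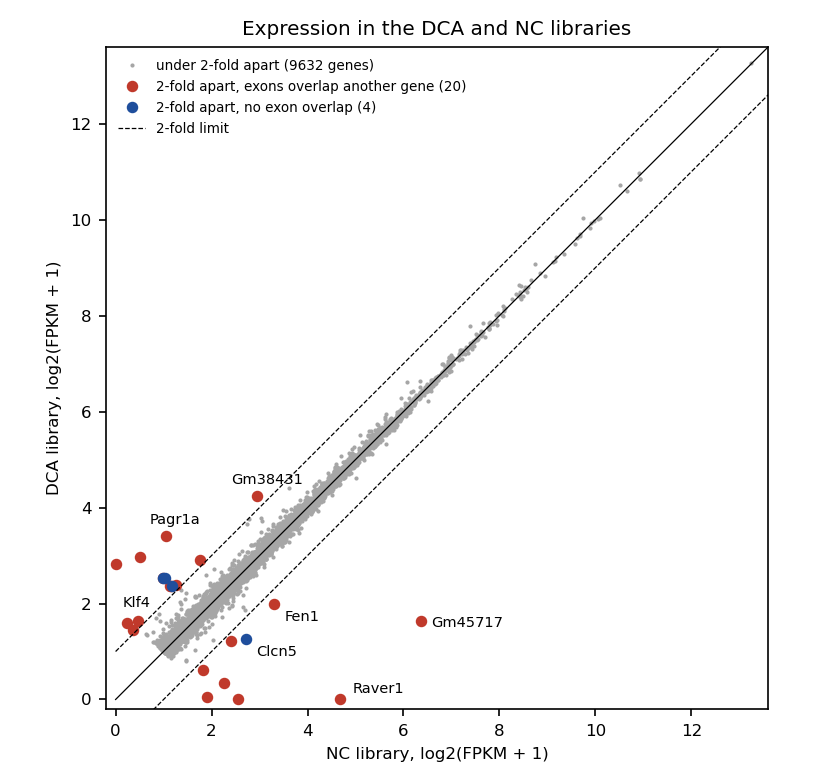
Each point is 1 of the 9656 tested genes, with log2(FPKM + 1) in the NC library on the horizontal axis and in the DCA library on the vertical axis, and the dashed lines mark the 2-fold limit. Of the 24 genes beyond the limit, 20 have exons that overlap another annotated gene, drawn in red, and 4 do not, drawn in blue.

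Among genes with no overlapping annotated exon, Klf4, Stfa3 and the non-coding 5730403I07Rik were at least 2-fold higher in DCA, and Clcn5 was at least 2-fold lower. Klf4, a Krüppel-like transcription factor of monocyte differentiation (ENSMUSG00000003032, GRCm38 chromosome 4, 55527143 to 55532466, minus strand), had 4.12 FPKM in DCA and 1.26 in NC, from 1027 and 330 reads. Its ratio was 3.26 (95% interval 2.87 to 3.70). Clcn5, which encodes an endosomal chloride and proton exchanger (ENSMUSG00000004317, chromosome X, 7153810 to 7319358, minus strand), had 1.399 FPKM in DCA and 5.59 in NC, a ratio of 0.250 (0.236 to 0.265). Stfa3 rested on 112 and 24 reads, a ratio of 4.88 (3.12 to 7.94). It belongs to a family of similar stefin A genes, so its reads are uncertain, and the related Stfa2l1 had a ratio of 1.03 (0.953 to 1.11). 5730403I07Rik had 553 reads in DCA and 124 in NC, a ratio of 4.67 (3.83 to 5.72). Stfa3, 5730403I07Rik and Clcn5 were chosen after their values were seen.

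The other 20 genes beyond the limit have exons that overlap another annotated gene, on the same or the opposite strand. This makes the values of most of them uncertain. Raver1, which encodes an RNA-binding protein (ENSMUSG00000010205, chromosome 9, 21074158 to 21092008, minus strand), was listed at 0 in DCA and at 24.6 FPKM in NC, from 0 and 5058 reads. Of its 3470 exonic bases, 3459 (99.7%) also lie in exons of Gm38431, an annotated read-through gene (chromosome 9, 21067514 to 21091997, minus strand), which had 7265 reads in DCA and 2851 in NC. Summed over both genes, the reads were 7265 in DCA and 7909 in NC, a ratio of 0.961 (0.931 to 0.993). Gm45717 had 59 reads in DCA and 2390 in NC, and the overlapping Ifitm2 and Ifitm5 lay the other way, with 8196 and 6449 reads together, a ratio of 1.33 (1.29 to 1.37). Pagr1a (ENSMUSG00000030680, chromosome 7, 127015033 to 127017352, minus strand) had 9.55 FPKM in DCA and 1.07 in NC, while the genes overlapping it had 531 and 1795 reads, a ratio of 0.310 (0.280 to 0.341). The table gives the symbol Pagr1a to an overlapping identifier, named Gm42742 in the annotation, so the assignment between them is open. Fen1, a flap endonuclease of DNA replication (ENSMUSG00000024742, chromosome 19, 10199132 to 10204169, minus strand), had 2.98 FPKM in DCA and 8.84 in NC, a ratio of 0.337 (0.318 to 0.357). The overlapping Tmem258 did not lie the other way, with 1585 and 1591 reads, a ratio of 1.04 (0.972 to 1.12). Snhg5, a host gene of small nucleolar RNAs and the only tested member of the list of long non-coding RNAs, had 4.15 FPKM in DCA and 1.21 in NC, a ratio of 3.42 (3.04 to 3.87). Its exons overlap annotated genes that have no value here.

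**Figure D2:**
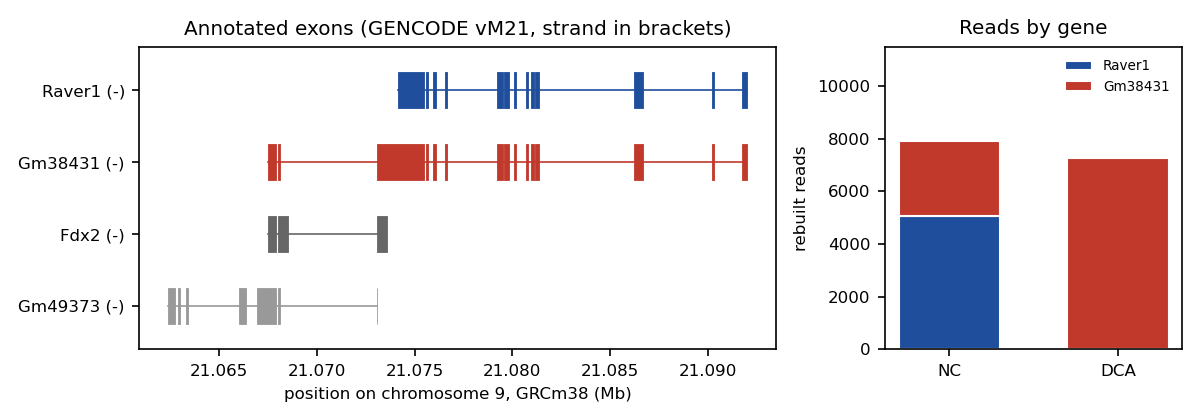
The left panel maps the annotated exons (boxes) of Raver1, Gm38431, Fdx2 and Gm49373 on chromosome 9 of GRCm38, with position in megabases on the horizontal axis, and the right panel stacks the rebuilt reads of Raver1 and Gm38431 in each library. The 5058 reads of Raver1 in NC have no counterpart in DCA, where Gm38431 has 7265 reads, while the sums of both genes are 7909 and 7265.

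Among genes with a mean FPKM of at least 5 whose symbols are more than a predicted gene number, which passes over Gm38431 and Gm10800 on the higher side and Gm45717 on the lower, the highest differences after Pagr1a were those of Rnasek, with a ratio of 2.05 (1.86 to 2.26), Pde2a, a phosphodiesterase, at 1.78 (1.70 to 1.87), and Cox6a2 at 1.77 (1.53 to 2.06), all of which overlap another gene. The Pde2a identifier rested on 4720 reads in DCA and 2770 in NC and is Gm45837 in the annotation, and the table has another identifier with the symbol Pde2a, at 97 and 1778 reads. Ccr7, the chemokine receptor of migrating dendritic cells and lymphocytes (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077, minus strand), overlaps none and had 12.2 FPKM in DCA and 7.27 in NC, a ratio of 1.68 (1.54 to 1.83). Prg2, the major basic protein of eosinophil granules (ENSMUSG00000027073, chromosome 2, 84980461 to 84983632, plus strand), had 97.0 and 65.9 FPKM, a ratio of 1.47 (1.41 to 1.54). Blk, a kinase of B cells, had a ratio of 1.42 (1.33 to 1.51), and Ddit4, a stress-induced inhibitor of mTORC1, 1.45 (1.29 to 1.62). Apoc2, which overlaps another gene, and Rflnb, Pop7 and Asprv1, which do not, had ratios between 1.36 and 1.46. On the lower side, Raver1 and Fen1 were followed by Evi2b at 0.761 (0.722 to 0.801) and Apmap at 0.763 (0.718 to 0.812), both overlapping another gene. Plau, the urokinase plasminogen activator, had 38.8 FPKM in DCA and 48.6 in NC, a ratio of 0.799 (0.777 to 0.823). Lpl, lipoprotein lipase (ENSMUSG00000015568, chromosome 8, 68880491 to 68907448, plus strand), had 73.1 and 90.2 FPKM, a ratio of 0.811 (0.802 to 0.820) that rests on 54787 and 70743 reads. Pigyl, Bop1, Slc25a33, Rbm42, Gins1 and Snrpf had ratios between 0.765 and 0.807. Of these, Bop1, Slc25a33, Rbm42 and Snrpf overlap another gene.

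Of the 29 lists with enough tested members, 7 stood above and 4 below the random lists, where 1.45 would fall outside by chance if genes varied independently. The neutrophil and lymphocyte markers had the largest median differences among the placed lists. All 20 neutrophil markers were higher in DCA, with a median ratio of 1.17 (interquartile range 1.10 to 1.23) and a percentile of 100. The calgranulins S100a8 and S100a9 had ratios of 1.22 (1.21 to 1.24) and 1.155 (1.14 to 1.17), at 1043 and 1699 FPKM in DCA. Retnlg, Ngp and the granule protease gene Elane had ratios of 1.27 (1.25 to 1.301), 1.18 (1.16 to 1.202) and 1.18 (1.1304 to 1.23). The 9 tested lymphocyte markers had a median ratio of 1.23 (interquartile range 1.19 to 1.27) and a percentile of 100. They included the B-cell receptor components Cd79a at 1.27 (1.22 to 1.32) and Cd79b at 1.24 (1.196 to 1.28), and Pax5, a transcription factor of B cells, at 1.22 (1.17 to 1.26). Mast cell and basophil markers were higher in 7 of 7 members, with a median ratio of 1.065 and a percentile of 96.8, short of the limit. Dendritic cell markers were higher in 8 of 9, at a median of 1.05 and percentile 95.7. Of that list Ccr7 passed 1.5-fold, and Siglech and Ly6d had ratios of 1.25 (1.202 to 1.29) and 1.22 (1.17 to 1.28). Across settings the mast cell and basophil list ranged from percentile 88.7 to 99.65 and the dendritic cell list from 80.2 to 99.62, on either side of the limit.

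Macrophage identity genes were lower in 19 of 27 members, with a median ratio of 0.967 (interquartile range 0.938 to 1.003) and a percentile of 0.115. The complement genes C1qa and C1qb had ratios of 0.896 (0.853 to 0.942) and 0.907 (0.884 to 0.930). Trem2, a lipid-sensing receptor, had a ratio of 0.900 (0.882 to 0.919). Adgre1, which encodes the macrophage antigen F4/80, had 61.6 FPKM in DCA and 65.7 in NC, a ratio of 0.938 (0.922 to 0.953), and Csf1r, the M-CSF receptor, 90.2 and 92.3, a ratio of 0.977 (0.967 to 0.988). Lyz2, a lysozyme gene shared by macrophages and neutrophils, had a ratio of 1.01 (1.01 to 1.02). Lysosomal genes were lower in 24 of 30, with a median ratio of 0.977 and a percentile of 0.78. The cathepsins Ctsb and Ctsl had ratios of 0.949 (0.946 to 0.952) and 0.907 (0.893 to 0.921). The percentile of the lysosomal list was 3.32 once genes with overlapping exons were left out, an alternative chosen after seeing the data. Osteoclast markers were lower in 6 of 9, at a median of 0.974 and percentile 6.94, and passed the limit in 3 other settings. These lower values stood beside the neutrophil median of 1.17 and the lymphocyte median of 1.23 in the same pair of libraries.

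**Figure D3:**
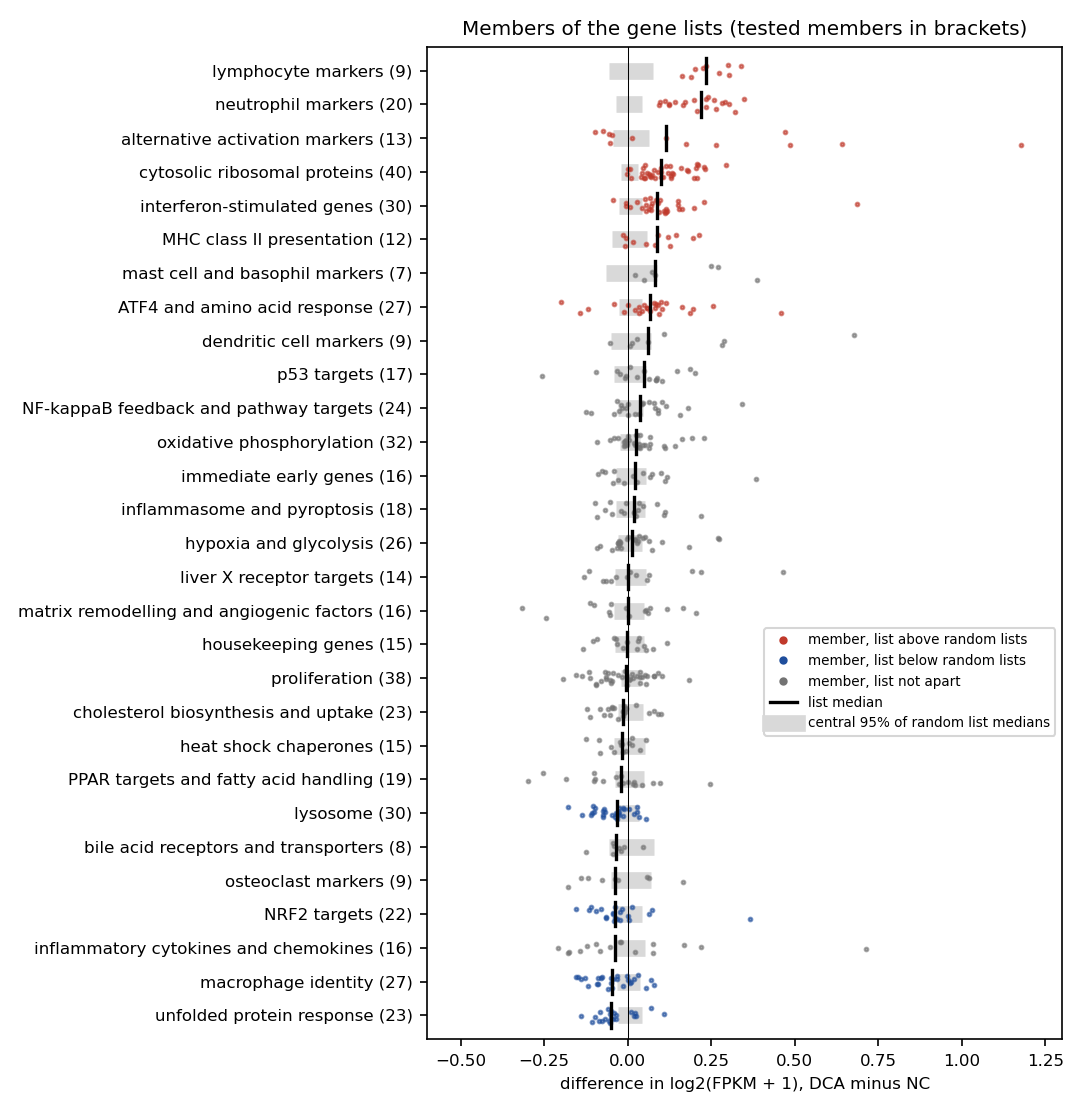
Each point is a tested member of a gene list, placed on the horizontal axis by its difference in log2(FPKM + 1), DCA minus NC, with the list median as a black bar and the central 95% of the medians of 10000 matched random lists as a grey band. Red and blue mark the 7 lists above and the 4 lists below the random lists, and the neutrophil and lymphocyte markers lie furthest to the right.

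Cytosolic ribosomal protein genes were higher in DCA in 39 of 40 members, with a median ratio of 1.075 (interquartile range 1.04 to 1.133) and a percentile of 100, and Rpl28, the remaining member, had a ratio of 0.999 (0.947 to 1.06). Rps15, Rpl22 and Rps18 had ratios of 1.133 (1.11 to 1.16), 1.18 (1.148 to 1.22) and 1.18 (1.14 to 1.22), and no member reached 1.5-fold. Targets of ATF4, the transcription factor of the amino acid response, were higher in 22 of 27, with a median ratio of 1.06 and a percentile of 99.95. Members of serine synthesis were among them: Phgdh at 1.129 (1.07 to 1.19), Psat1 at 1.09 (1.05 to 1.127) and Psph at 1.24 (1.12 to 1.37). Atf4 itself had a ratio of 1.03 (1.01 to 1.06), while the stress factors Ddit3, Chac1 and Atf3 had ratios of 0.970 (0.904 to 1.04), 0.883 (0.762 to 1.02) and 0.864 (0.825 to 0.903). Both lists were measured beside the neutrophil and lymphocyte medians of 1.17 and 1.23. Genes of the unfolded protein response, which act in protein folding in the endoplasmic reticulum, were lower in 17 of 23, with a median ratio of 0.963 and a percentile of 0.05. The chaperone Hspa5 had a ratio of 0.928 (0.917 to 0.939) and the disulfide isomerase Pdia6 0.905 (0.885 to 0.926). NRF2 targets were lower in 16 of 22, at a median of 0.974 and percentile 1.2. Hmox1, haem oxygenase 1, had 146.9 FPKM in DCA and 155.4 in NC, a ratio of 0.945 (0.927 to 0.964). Nqo1, another NRF2 target, went the other way at 1.36 (1.19 to 1.55), and with the mean of the members in place of the median the percentile of the list was 5.1. Heat shock chaperones and p53 targets did not stand apart, at median ratios of 0.988 and 1.04 and percentiles of 14.9 and 95.7. With pseudocount 5 the p53 targets passed the limit, at 98.13.

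Interferon-stimulated genes were higher in 27 of 30 members, with a median ratio of 1.07 (interquartile range 1.05 to 1.14) and a percentile of 100. Ifit3b passed 1.5-fold, with 1.55 FPKM in DCA and 0.583 in NC from 175 and 69 reads, a ratio of 2.65 (1.998 to 3.56). It is a close copy of Ifit3, which had a ratio of 1.21 (1.07 to 1.38), so the share of reads between them is uncertain. Oasl2 and Rigi had ratios of 1.128 (1.08 to 1.17) and 1.14 (1.10 to 1.19). MHC class II presentation genes were higher in 9 of 12, with a median ratio of 1.07 and a percentile of 99.75. H2-Aa, H2-Eb1 and Cd74 had ratios of 1.11 (1.08 to 1.133), 1.151 (1.12 to 1.18) and 1.09 (1.08 to 1.11). B cells and dendritic cells also express these genes, and the lymphocyte markers were higher by a median of 1.23 in the same libraries. Alternative activation markers had a median ratio of 1.130 with a wide interquartile range of 0.964 to 1.496, were higher in 8 of 13 members, and stood at percentile 99.98. Klf4 and Ccl22 passed 1.5-fold, Ccl22 at 1.89 (1.62 to 2.20), and Clec10a and Alox15 were at 1.59 (1.47 to 1.71) and 1.496 (1.346 to 1.66) before the pseudocount. Dendritic cells also express Ccl22 and Clec10a, and eosinophils Alox15, and in the same libraries Ccr7 of dendritic cells was at 1.68 and the eosinophil gene Prg2 at 1.47. The mannose receptor gene Mrc1 was at 0.964 (0.944 to 0.984). This list did not stand apart without a filter, at percentile 35.5, and its median turned negative after rescaling each library to 1e6, at -0.0123 and percentile 38.6, and with a mean FPKM of at least 5, at -0.0495 and percentile 2.8.

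Inflammatory cytokine and chemokine genes were lower in 10 of 16 members, with a median ratio of 0.973 and a percentile of 2.54, just short of the limit, which was passed in 8 other settings. The mean of their differences lay above 0, at 0.011. Tnf had 9.89 FPKM in DCA and 11.6 in NC, a ratio of 0.854 (0.801 to 0.910), and Ccl3 and Ccl7 were at 0.903 (0.857 to 0.953) and 0.917 (0.883 to 0.953). Ccl5 was at 2.36 (1.74 to 3.23), from 142 and 63 reads. Il1b had a ratio of 1.06 (1.0015 to 1.11). Il6, below the filter with 58 and 41 reads, had a ratio of 1.48 (0.976 to 2.27), which includes equality. Il10, also below the filter, had 13 reads in DCA and 49 in NC, a ratio of 0.278 (0.138 to 0.520). Arg1 had 26 and 38 reads, and a difference was not detectable at this depth, with a ratio of 0.716 (0.417 to 1.21). NF-kappaB targets were higher in 16 of 24, at a median of 1.03 and percentile 94.0, which was 41.4 once genes with overlapping exons were left out. Inflammasome and pyroptosis genes were higher in 10 of 18, at a median of 1.01 and percentile 71.7, and their median was negative with a mean FPKM of at least 5, at percentile 33.2. The inflammasome sensor Nlrp3 had 12.5 FPKM in DCA and 12.6 in NC, a ratio of 0.993 (0.958 to 1.03). Immediate early genes were at a median of 1.02 and percentile 74.8, and their median was negative without genes with overlapping exons, at percentile 13.8.

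The list of bile acid receptors and transporters had 8 tested members, 7 of them lower, with a median ratio of 0.968 and a percentile of 10.2. The counting interval excluded equality for only 1 of the 8, on the lower side. Without a filter on low values the median of the list lay just above 0, at percentile 45.1. The receptor gene Gpbar1 (TGR5; ENSMUSG00000064272, chromosome 1, 74278550 to 74279624, plus strand) had 5 reads in DCA and was listed at 0 in NC. The vitamin D receptor Vdr, which binds secondary bile acids, had 0.627 and 0.580 FPKM, below the filter, a ratio of 1.08 (0.902 to 1.296). S1pr2, a receptor for conjugated bile acids, had 9.94 FPKM in DCA and 10.01 in NC, a ratio of 0.993 (0.955 to 1.03). The efflux transporter Abcc3 was at 0.906 (0.872 to 0.941). Genes of cholesterol synthesis and uptake were lower in 18 of 23, at a median of 0.990 and percentile 13.61. Their counting intervals lay below equality for 5 members and above it for 3. Liver X receptor targets were at a median of 1.002 and percentile 43.5, with 7 higher and 7 lower. The median lay so close to equality that its sign depended on the scaling. Centring and upper quartile scaling move all genes nearly alike, and the list was at percentiles 43.53 and 42.67 with them. Abca1, a cholesterol exporter, was at 0.947 (0.924 to 0.971). PPAR targets and fatty acid genes were at a median of 0.984 and percentile 11.7, with 8 of 19 members higher, and did not stand apart. Single members went both ways, such as Cd36 at 0.878 (0.866 to 0.889), Pparg at 0.755 (0.683 to 0.834) and Hadhb at 1.11 (1.03 to 1.205).

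Proliferation genes did not stand apart, with 17 of 38 higher, a median of 0.996 and a percentile of 20.2. Mki67, a marker of cycling cells, was at 1.03 (1.01 to 1.04), and Mcm6 and E2f1, of the DNA replication phase, were at 0.907 (0.887 to 0.928) and 0.861 (0.818 to 0.906). Hypoxia and glycolysis, oxidative phosphorylation, matrix remodelling and angiogenic factors, and housekeeping genes were at percentiles of 63.2, 92.0, 43.9 and 38.0. Across settings the matrix list ranged from 0.76 to 81.37, past the limit in 1 of them. Oxidative phosphorylation ranged from 65.31 to 94.17 and housekeeping genes from 26.35 to 84.23. Stromal cell markers had 3 tested members, 2 higher and 1 lower, and erythroid and megakaryocyte markers had 2, both lower with a median ratio of 0.906, too few to be placed. Of these, Pf4, which macrophages also express, was at 0.857 (0.813 to 0.902). Of the 13 mitochondrially encoded genes none was analysed here.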

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

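No paired analysis was possible because there is 1 library per group and no result comes from a test; for the same reason no library could be left out. Matching on exon length, leaving out genes with overlapping exons and FPKM rebuilt with merged exon lengths were chosen after seeing the data. The lists of neutrophil markers and ribosomal proteins stayed at percentile 100 in 13 settings, and those of lymphocyte markers (99.8 to 100), interferon-stimulated genes (99.5 to 100), ATF4 targets (98.8 to 99.98), MHC class II genes (98.4 to 99.87), macrophage identity (0.03 to 1.41) and the unfolded protein response (0.02 to 1.02) also kept their side of the limit. The 13 settings include the main one and centring on the trimmed mean, which shifts all genes alike and cannot move a percentile. A percentile of 100 is the end of the scale, so it cannot show a change in size. Of the comparisons of named genes with an alternative, 271 kept their side of 1.5-fold, 4 passed it and 7 fell below it; the 7 came from pseudocount 5, which shrinks genes with low FPKM. Genes with few reads have wide intervals whatever the setting.

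The counts of genes 2-fold higher (15) and lower (9) were 25 higher with pseudocount 0.1, 3 and 2 with pseudocount 5, 2 and 3 with a mean FPKM of at least 5, and 82 and 34 after rescaling each library to 1e6, which multiplies FPKM and so weakens filter and pseudocount (11706 genes tested). They were 33 and 15 at 1.5-fold, 3 and 5 at 3-fold, and 3 and 1 without overlapping genes. Counting intervals excluded equality for 2482 and 1927.

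Alternative activation changed sides: percentile 35.48 without a filter, 2.8 with a mean FPKM of at least 5 and 38.58 after rescaling, where more or fewer of its low members count. Calls were lost for NRF2 targets with the mean (5.1) and for the lysosome without overlapping genes (3.32). Inflammatory cytokines and chemokines passed the limit with pseudocount 5 (0.56), a mean FPKM of at least 5 (1.01), rescaling (1.535), upper quartile scaling (2.26), no matching (2.39), length matching (1.56), no overlapping genes (0.03) and merged exons (0.92). Mast cell and basophil markers passed with pseudocount 5 (99.65), no filter (98.19), rescaling (97.98) and the mean (98.83), but fell to 88.7 with length matching. Dendritic cell markers passed with a mean FPKM of at least 5 (99.56), the mean (99.62) and merged exons (99.23), but fell to 80.16 without a filter. Osteoclast markers passed with no filter (1.18), a mean FPKM of at least 5 (2.02) and no overlapping genes (1.69). Cholesterol genes with a mean FPKM of at least 5 (2.06), matrix genes after rescaling (0.76) and p53 targets with pseudocount 5 (98.13) passed in 1 setting each. Among lists that did not stand apart, the median changed sign for bile acid genes without a filter (45.12), where low members enter, for inflammasome genes (33.24) and liver X receptor targets (11.99) with a mean FPKM of at least 5, for immediate early genes without overlapping genes (13.83), for inflammatory genes with the mean (48.99), for liver X receptor targets under each scaling and merged exons, and for matrix and housekeeping genes, whose medians were near 0, in several settings. Centring and upper quartile scaling move all genes nearly alike, so a changed sign there says little about a list. Without overlapping genes NF-kappaB targets were at 41.39. The cause of the other changes was not tested.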

Other observations

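The genes named here were chosen after their values were seen. Epx, the eosinophil peroxidase, had 2.99 FPKM in DCA and 1.57 in NC, a ratio of 1.90 (95% counting interval 1.65 to 2.19), beside the ratio of 1.47 for Prg2, another eosinophil granule gene. Ccr2, the receptor that brings monocytes out of the marrow, was at 1.24 (1.22 to 1.26), and Ly6c2, which has close copies, at 1.19 (1.16 to 1.22). The transcription factor Klf2 was at 1.32 (1.25 to 1.39). Mmp8, a collagenase gene of neutrophils, was closer to equality, at 1.04 (1.02 to 1.06). The growth factor gene Igf1 was at 0.818 (0.787 to 0.851) and the caveolin gene Cav2 at 0.834 (0.802 to 0.867). Klf2 belongs to the list of immediate early genes, and Mmp8 and Igf1 to that of matrix remodelling and angiogenic factors. Neither list stood apart in the main setting, at percentiles of 74.8 and 43.9. The other genes named here are single genes with no list behind them.

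The tests of overlapping genes lying the other way, of a larger share of other marrow cells, of all other cell types raised alike, and of counting error were chosen after the result was seen, as were the settings with exon length matching and without overlapping genes.

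The first pattern is the 24 genes at least 2-fold apart. Counting error alone was argued against by the simulation, where no unchanged gene was 1.5-fold apart, though it held no PCR copies. The counting intervals of all 24 genes excluded equality, but this was nearly fixed in advance, because the same values picked these genes. Of these genes, 83.33% had an exon overlapping another annotated gene, against a median of 41.7% (central 95% 20.8 to 58.3%) in random sets matched on expression, and in 15 of the 18 with such a gene in the table, at 12 loci, the overlapping genes lay the other way beyond counting error, against a median of 4 and an upper limit of 8 (of the central 95%) in random sets. For these 15 a candidate explanation is that reads shared between overlapping genes were assigned differently in the 2 libraries. For some, the difference is small beside the reads of the overlapping genes, whose direction then says little. Ptprcap had 5 reads in DCA and 326 in NC, beside 18592 and 18324 in its overlapping genes. Gm20708 had 205 and 19, beside 8907 and 9643. A change in transcript use with DCA was not tested. Reads shared between overlapping genes were argued against for 1 gene, D030028A08Rik, whose overlapping genes had a ratio of 0.997 (0.959 to 1.04) where 0.724 was needed. The 4 genes without any overlap (Klf4, Stfa3, 5730403I07Rik and Clcn5) cannot share reads in this way by definition, so they tested nothing here. For them the spread between cultures and reads shared with related genes stay open. Reads shared between overlapping genes stay open for Gm49416, whose difference is small beside the reads of its overlapping genes. The same holds for Fen1, Snhg5 and Gm20559, which overlap annotated genes not analysed here.

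The second pattern is the higher level of markers of other marrow cells with lower macrophage markers. Gene length bias was argued against, for the neutrophil markers, since that list stayed at percentile 100 among random lists matched on exon length, while the mast cell and basophil list fell from 96.8 to 88.7. A larger share of other marrow cells in the DCA library stays open, because 100% of the tested neutrophil markers being higher restates the pattern. The 2 tested erythroid and megakaryocyte markers were lower, at a median of 0.906, but cannot decide it. Macrophages also express Pf4, and the counting interval of the other marker included equality. Whether all other cell types were raised alike cannot be told apart from unequal shifts: the median of the mast cell and basophil list, 1.065, lay below the neutrophil interquartile range of 1.105 to 1.229, but its own range of 1.059 to 1.274 overlapped it. Whether such a share came from DCA, which may act on survival or maturation, or from the culture dish is not decided with 1 library per group.

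The third pattern is the higher level of cytosolic ribosomal protein genes, which are short. Across tested genes the difference was weakly related to exon length, with a Spearman rho of -0.108 across genes and a median log2 difference of 0.027 in the shortest of 5 length classes against -0.0013 in the longest. As the whole cause, gene length bias was argued against by the percentile of 100 among random lists matched on expression and exon length, though the matching used only those 5 classes. A larger share of cells rich in ribosomal transcripts, a difference in RNA handling between libraries and an effect of DCA on these genes were not tested and could each remain.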
